A study of Mus musculus with 6 samples.

How the data were processed

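Gene expression was measured in mouse bone marrow cultures of the C57BL/6 strain with 6 single-colour Illumina bead arrays of 45281 probes each. Per the labels' protocols, RNA was extracted with Trizol, cleaned with RNeasy columns and treated with DNase I, its quality was checked on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion MessageAmp kit. The authors deposited a table of intensity values that were not normalized, which per the file headers are the mean bead brightness of each probe on each array. The same table gives, per the file headers, a detection p-value for every probe and array. These p-values move in steps that imply 936 negative control bead types. The scanner software and its version are not given in the sources used here.

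The authors also deposited processed intensity values of the same arrays. Their scale was linear, with a lowest value of -51.1, a highest value of 42993 and nearly identical sorted values on every array, so they were taken as background-subtracted and quantile normalized. The medians of the 6 columns were 7.89, 7.88, 7.89, 7.88, 7.85 and 7.89. Each column had a rank correlation of 1 with its own array in the other table and at most 0.881 with any other array. The exact method behind these values is not given in the sources used here, and they served as an alternative only.

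Intensities were background-corrected with the normexp method of limma 3.58.1 in R 4.3.3, which used the detection p-values in place of control probes, with an offset of 16. The values were then quantile normalized and put on the log2 scale. A table of platform annotation paired 34885 probes with 1 gene symbol and 18 with several, and 10378 probes are unnamed here. Probes with several symbols were not named. Of the Entrez identifiers, 99.8% were found in the RefSeq gene table and 0 symbols changed through it. Of the 19057 genes, 9172 had more than 1 probe, and the probe with the highest mean over the 6 arrays stood for its gene. A probe with a detection p under 0.01 was called detected. Tests across arrays used the 9221 genes detected on at least 2 of the 6 arrays. No genome was used, so no coordinates are given.

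The samples fall into 3 stages and 2 treatments with 1 array for each combination. The treatment was tested across stages with an additive limma model with stage as a block, which leaves 2 residual degrees of freedom, moderated with a prior of 3.73 degrees of freedom. The same model gave immature DC minus pre-DC and mature DC minus immature DC, with treatment as a block. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. The residual for the treatment is how its difference varies between the 3 stages, so a response that differs by stage counts as error. A gene that responds in some stages only is thus unlikely to pass. Nothing in the labels says that the cultures were independent, so the p-values measure only this spread between these arrays, part of which may be technical. Within a stage there is no replicate and no test was made. There, genes detected on at least 1 of the 2 arrays were counted at 2-fold, and the median of each gene list was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins. Where a gene was not above background on any array of one side, the fold is a bound, written as "at least N-fold". It sets the brighter side against the lowest signal among detected probes, or the probe's own signal where that was higher. No fold is given where both sides were below background.

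The 31 gene lists held 614 entries, of which 556 had a named probe and 448 were among the tested genes. They covered MHC class II presentation, MHC class I presentation, costimulation and maturation, inhibitory and tolerogenic genes, inflammatory cytokines, chemokines and receptors, the p38 MAPK pathway, ERK feedback and immediate early genes, NF-kB members and targets, PPARG and lipid targets, cholesterol synthesis, interferon response, cell cycle, glycolysis, oxidative stress, lysosome and autophagy, unfolded protein and amino acid stress, and ribosomal proteins. Markers of cell types covered DC identity, macrophages, neutrophils and granules, monocytes, eosinophils, mast cells and basophils, progenitors, erythroid cells, B cells, T cells, NK cells, plasmacytoid DC and stroma. Lists were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation, on ranks and with fry. The lists, the tests, the thresholds, the alternatives and the rule for naming genes were set before the data were examined, except where the closing text says otherwise.

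The named genes were, across stages, up to 15 in each direction past the threshold, filled where fewer passed by the genes with the largest smallest difference among those that went the same way in all 3 stages. Within a stage they were the 10 highest and 10 lowest, and for each step between stages the 10 highest and 10 lowest past the threshold. List members at least 2-fold different were added, at most 4 for each list. A set of 16 genes was always named, of which 14 had a named probe. Nfkb1 and Il12b are therefore not analysed here. Il10 was not above background on any array.

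The steps were tested on simulated data. Of 200 genes changed 2-fold among 9221, the test across stages recovered 163 (81.5%) with 6 false calls, and of 200 changed 4-fold it recovered 197 (98.5%) with 13 false calls. For immature DC minus pre-DC, 107 of 200 genes changed 2-fold (53.5%) and 194 changed 4-fold (97%) were recovered, with 5 and 9 false calls. Within a stage, all 200 genes changed 4-fold passed the 2-fold limit and 0 unchanged genes did. A list shifted by -0.25 on the log2 scale was called in 20 of 20 simulations, and 1 of 600 other list tests was called. The simulated genes varied independently of each other, unlike real genes. Simulated pair differences had an SD of 0.21, against 0.27, 0.34 and 0.38 in the real pre-DC, immature DC and mature DC pairs. Few false calls at 2-fold could therefore arise within a stage. No simulated treatment effect differed between stages, so the shares recovered across stages may not hold for the real data. Of 31 unchanged lists, 0 had a median outside the 2.5th to 97.5th percentile of random lists. This check too used independent genes. Random lists are drawn gene by gene, so for a list whose members vary together these limits are too narrow.

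The alternatives tried were no background correction, scaling to the 75th percentile, the authors' processed values, an offset of 50, no detection filter, detection on all arrays of the comparison, the mean of all probes of a gene, moderation with a trend and robust fitting, no stage block, other fold limits, other list tests, and leaving out each array or pair in turn. All 6 arrays were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.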

Results

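Bone marrow cells of C57BL/6 mice were cultured with GM-CSF at 20 ng/ml, a cytokine under which marrow progenitors grow into dendritic cells (DC), to ask how blocking p38 MAP kinase in the progenitors affects the DC that arise and their ability to stimulate immunity. The cultures held either SB202190, an inhibitor of p38 kinases that the labels give as 1.5 mM (a unit that was not checked here), or the solvent DMSO at 0.1%. RNA was profiled after 2 days of culture (pre-DC), from the semi-adherent cells at day 7 (immature DC) and after a further 48 h with TNF-a and IL-1b at 10 ng/ml each (mature DC). The labels do not say whether the inhibitor stayed in the medium during maturation. Each stage had 1 array with DMSO and 1 with SB202190, which made 3 arrays for each treatment and 2 for each stage. Between 14623 and 15328 of the 45281 probes were detected on each array, the fewest on the mature DC array with SB202190. Median intensities ran from 120.5 on that array to 146.2 on the pre-DC array with SB202190. The number of arrays limits the precision of every value.

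Genes were ranked across the 3 stages by the smallest of their 3 pair differences, among those that differed the same way in all 3 pairs. Among the highest-ranked lower genes with SB202190, Ctsk, a lysosomal cysteine protease, had a mean log2 difference of -1.31 (SE 0.18), Nr1h3, the liver X receptor alpha, -1.29 (SE 0.21), the eosinophil-associated ribonuclease gene Ear10 -1.25 (SE 0.23) and Mrc1, the macrophage mannose receptor, -1.09 (SE 0.19). Pparg, a nuclear receptor that drives lipid storage genes, had -0.76 (SE 0.15). The highest-ranked higher genes included Mycl, a MYC family gene expressed in DC (0.86, SE 0.11), Irf4, a transcription factor of conventional DC (0.59, SE 0.11), Ciita, the master activator of MHC class II genes (0.56, SE 0.10), and Relb, an NF-kB subunit (0.52, SE 0.11). Each of these differences had the same sign in all 3 pairs of arrays.

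None of these genes passed the test, in which variation of the difference between stages counts as error. With limma, 0 of 9221 genes reached an adjusted p of 0.05; the smallest adjusted p was 0.445, shared by each gene named above, and 854 genes had an unadjusted p under 0.05. The count was also 0 without the stage block and 1 with trend and robust moderation (Wfdc17, lower, adjusted p = 0.0467). With the immature DC pair or the mature DC pair left out, 0 genes passed. Without the pre-DC pair, 41 genes passed in limma, 19 higher and 22 lower. Among them were Ctsk, Nr1h3, Ear10, Hebp1, Wfdc17, Pmp22, F7, Gm5150 and Cd40 (limma adjusted p from 0.0284 for Ctsk to 0.0490 for Wfdc17). This fit rests on the immature and mature DC pairs alone, with 1 residual degree of freedom, and the labels do not give these pairs as separate cultures. Leaving out a single pre-DC array gave the same fit of the treatment and is no separate check, since the array that remains is fitted by its own stage term. At a mean difference of at least 2-fold, 1 gene was higher and 11 were lower.

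Of the p38 kinases, Mapk14, which encodes p38 alpha, had a mean log2 difference of -0.03 (SE 0.11) and its substrate kinase Mapkapk2 0.01 (SE 0.10). Mapk11, p38 beta, was detected on the pre-DC arrays alone, with a difference of -0.02 there. The sign for Mapkapk2 turned with 75th percentile scaling, to -0.0043. Probes of these genes measure transcript and not kinase activity, so they do not check the inhibition. Among the costimulatory genes, Cd40 had 0.74 (SE 0.24, limma adjusted p = 0.498), Tnfsf4, the OX40 ligand, 0.48 (SE 0.20, limma adjusted p = 0.54), Cd86 0.43 (SE 0.25) and Cd80 0.37 (SE 0.20). Cd83, a DC maturation marker, had -0.20 (SE 0.60), with pair differences of -2.22, 0.74 and 0.88 from pre-DC to mature DC and a mean of 0.81 without the pre-DC pair. The pre-DC pair also had the opposite sign for Cd86 (-0.33), Cd80 (-0.21), Ccr7 (-0.92) and Cd274 (-0.38), and without that pair the means were 0.80 for Cd86, 0.67 for Cd80, 0.75 for Ccr7, 0.24 for Cd274, 0.08 for H2-Ab1 and 1.11 for Cd40, which then passed (adjusted p = 0.0424). With all pairs, Ccr7, the receptor that guides DC to lymph nodes, had 0.19 (SE 0.34), the inhibitory ligand Cd274 0.03 (SE 0.16), the class II gene H2-Ab1 0.22 (SE 0.13) and the DC integrin Itgax 0.16 (SE 0.10). Tnfsf4 and Itgax were below background on both pre-DC arrays, yet the means and SEs given above include that pair. In the 2 measured pairs, immature and mature DC, the differences were 0.52 and 0.99 for Tnfsf4 and 0.20 and 0.18 for Itgax.

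As groups, genes of DC identity, NF-kB, interferon response, costimulation and antigen presentation rose with SB202190 in limma's camera test. None of these calls held in camera with an estimated correlation (adjusted p = 0.52 for costimulation and 0.515 for the other 5 lists). That setting called 0 of the 31 lists in every comparison made here, so a missing call there decides little by itself. The correlation it estimated was 0.52 for costimulation, 0.19 for MHC class II and 0.13 for MHC class I. It was 0.11 for DC identity, 0.064 for NF-kB and 0.014 for interferon response. Where it lies above the preset 0.01, the p-values at the preset may be too small. Of the 18 measured DC identity genes 15 were higher (median log2 0.34, camera adjusted p = 6.27e-05), and 6 of them, against 0 over all genes tested, passed in limma when adjusted over the list alone. Of 21 NF-kB members and targets 17 were higher (median 0.23, adjusted p = 6.27e-05), as were 17 of 20 interferon response genes (median 0.28, adjusted p = 8.41e-05). Costimulation and maturation genes were higher for 17 of 20 (median 0.29, adjusted p = 0.0025, though -0.20 in pre-DC), MHC class II presentation for 10 of 14 (median 0.17, adjusted p = 0.0268) and MHC class I presentation for 11 of 14 (median 0.11, adjusted p = 0.037). Adjusted over the list alone, 1 MHC class II gene passed and 0 of the other lists in this group.

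The groups that fell in the camera test were proliferation genes, granulocyte and monocyte markers, and lipid, lysosomal and oxidative stress genes. None of these 9 calls held either: for each the adjusted p = 0.515 with an estimated correlation. That correlation was 0.64 for cell cycle, 0.29 for cholesterol synthesis and 0.28 for neutrophil markers. It was -0.011 for oxidative stress, the lowest, and at most 0.22 for the others. Above the preset of 0.01, the p-values at the preset may be too small. Of 28 cell cycle genes 26 were lower (median -0.28, camera adjusted p = 9.2e-06). The neutrophil and granule markers were lower for 20 of 22 (median -0.17, adjusted p = 2.74e-04), the monocyte markers for 7 of 8 (median -0.31, adjusted p = 2.74e-04) and the eosinophil markers for 5 of 5 (median -0.39, adjusted p = 0.00244). PPARG and lipid targets were lower for 13 of 18 (median -0.22, adjusted p = 2.74e-04), lysosome and autophagy genes for 20 of 23 (median -0.14, adjusted p = 5.99e-04), cholesterol synthesis genes for 14 of 16 (median -0.14, adjusted p = 0.0108), oxidative stress genes for 12 of 17 (median -0.13, adjusted p = 0.0108) and inflammatory cytokines for 10 of 13 (median -0.09, adjusted p = 0.0416). Adjusted over the list alone, 5 PPARG and lipid targets, 3 monocyte markers, 2 lysosomal, 2 oxidative stress, 1 eosinophil and 1 cytokine gene passed as lower in limma, against 0 over all genes tested.

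In all, camera called 15 of the 31 lists, 6 up and 9 down. Camera on ranks also called 15, with glycolysis (adjusted p = 0.0417) in place of the inflammatory cytokines (adjusted p = 0.0504). With an estimated correlation 0 were called and by fry 0 (lowest fry adjusted p = 0.238), while fry's mixed test, for changes in either direction, called 4. Fry called 23 lists from pre-DC to immature DC and 6 from immature to mature DC, so it can call lists in these data. Other settings ended 3 calls: MHC class I with 75th percentile scaling (adjusted p = 0.051), the cytokines with detection on all arrays (0.058) or the mean of all probes (0.113), and oxidative stress with detection on all arrays (0.090). Leaving out 1 array ended single calls, and for the treatment it gives the same estimate as leaving out the pair of that stage. Without either immature DC array the cell cycle list had an adjusted p of 0.171, the cholesterol list 0.426, the MHC class II list 0.331 and the cytokine list 0.459. Without either mature DC array the costimulation list had 0.721, the MHC class I list 0.528 and the lysosome list 0.058. Without either pre-DC array the MHC class II list had 0.062 and the cytokine list 0.060.

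The remaining lists did not pass in camera. Macrophage markers had a median of -0.17 (adjusted p = 0.0581), inhibitory and tolerogenic genes -0.08 (adjusted p = 0.0596), glycolysis genes -0.09 (adjusted p = 0.0596), B cell markers -0.21 (adjusted p = 0.0581) and erythroid markers 0.25 (adjusted p = 0.0552). Progenitor markers had 0.20 (adjusted p = 0.131), NK cell markers 0.25 (adjusted p = 0.193), p38 MAPK pathway genes 0.03 (adjusted p = 0.279) and stromal markers 0.25 (adjusted p = 0.478). Chemokines and receptors had -0.04 (adjusted p = 0.411), unfolded protein and amino acid stress genes -0.02 (adjusted p = 0.393), ERK feedback and immediate early genes -0.09 (adjusted p = 0.455), mast cell and basophil markers 0.04 (adjusted p = 0.459), plasmacytoid DC markers -0.08 (adjusted p = 0.459), T cell markers -0.10 (adjusted p = 0.832) and ribosomal proteins 0.03 (adjusted p = 0.673). Adjusted over the list alone, 1 macrophage marker and 2 stress genes passed as lower and 1 stress gene and 1 erythroid gene as higher, and 0 of the other lists had a gene that passed in limma. Other settings made 5 of these lists pass. Macrophage markers passed in 6 alternatives (adjusted p from 0.0067 to 0.045), and without either pre-DC array (0.0155) or immature DC array (0.0272). Glycolysis genes passed as lower without background correction (adjusted p = 0.0280), with 75th percentile scaling (0.0393), the authors' processed values (0.0360), an offset of 50 (0.0491), the mean of all probes (0.0253) and on ranks. Inhibitory genes passed as lower without background correction (adjusted p = 0.0296) and with the authors' processed values (0.0162), B cell markers as lower with an offset of 50 (0.0439), and erythroid markers as higher with 75th percentile scaling (0.0452) and the mean of all probes (0.0244). Without either pre-DC array the erythroid (median 0.44, adjusted p = 0.00102) and mast cell (median 0.24, adjusted p = 0.0168) markers passed as higher, and without either immature DC array the B cell (median -0.30, adjusted p = 0.00158) and plasmacytoid DC (median -0.54, adjusted p = 0.00982) markers passed as lower, as did the inhibitory genes (adjusted p = 0.0416). B cell markers also passed without either mature DC array (median -0.25, adjusted p = 0.0147).

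**Figure D1:**
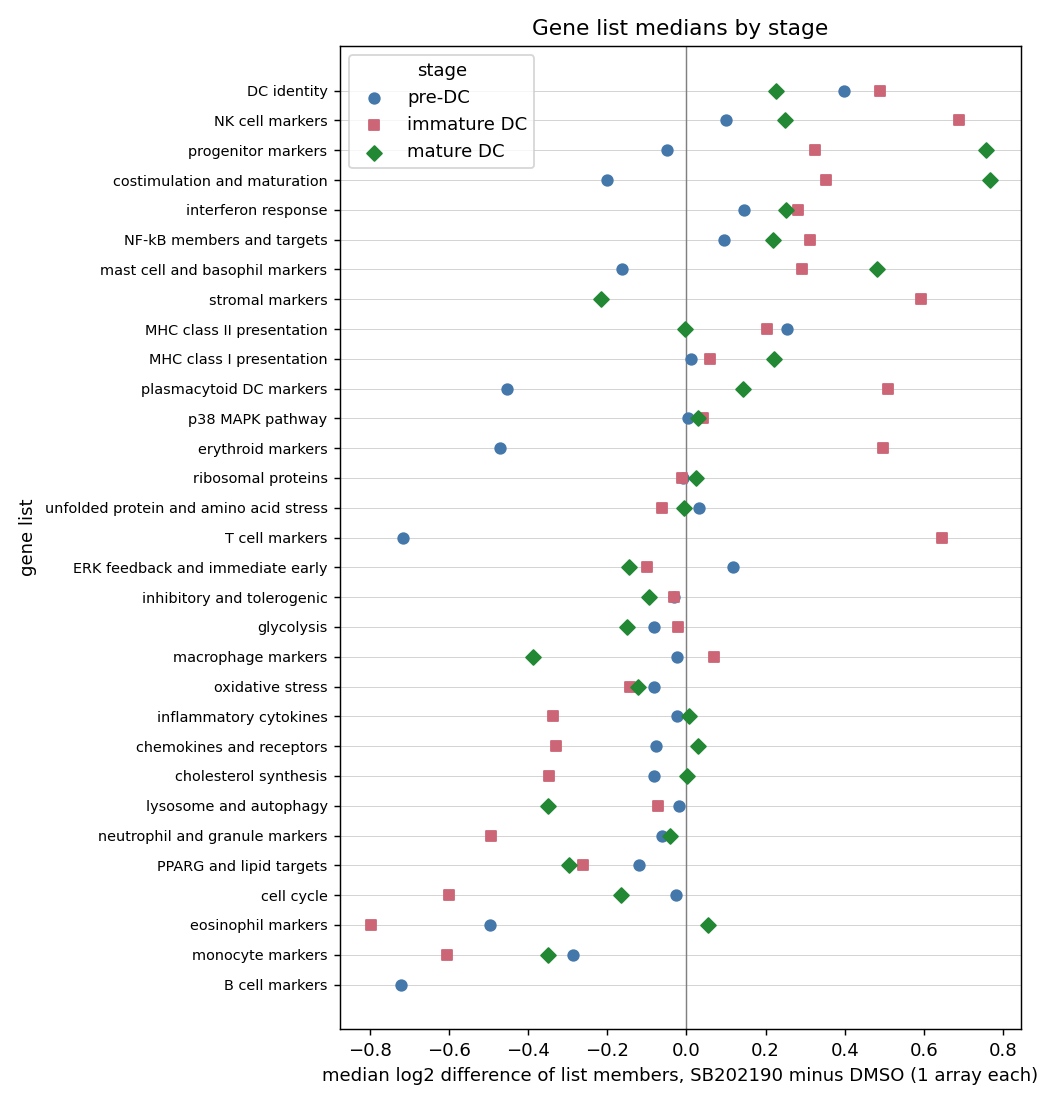
Median log2 difference (SB202190 minus DMSO) of the measured members of each gene list, with 1 point for each stage; lists with fewer than 3 members detected in a stage have no point there. DC identity lies above 0 in all 3 stages (0.40, 0.49 and 0.23) and monocyte markers below 0 in all 3 (-0.29, -0.60 and -0.35), while costimulation and maturation lies at -0.20 in pre-DC and at 0.35 and 0.77 in the later stages.

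Counted gene by gene, 3 genes were at least 1.5-fold higher and 15 at least 1.5-fold lower with SB202190 in each of the 3 pairs, where 0.283 and 0.395 would be found if the pairs were independent. The higher genes were Mycl, Simc1 and Ly86, which encodes a partner of a Toll-like receptor homologue, with means of 0.86, 0.70 and 0.64. The lower genes were Ctsk, Nr1h3, Ear10, Mrc1, Gm5150, F7, Pmp22, Wfdc17, Hebp1, Vldlr, Abcd2, Tcaf1, Sirpb1a, Ccdc80 and Apoc2, with means from -1.31 to -0.62. They include the lipoprotein receptor gene Vldlr (-0.77), the peroxisomal fatty acid transporter Abcd2 (-0.75) and the lipoprotein lipase cofactor Apoc2 (-0.62). Vldlr was below background on both immature DC arrays, so it was measured in 2 of the 3 pairs. Its place in the count and its mean both include the background-level difference of the immature DC pair (-0.66). Ctsk, Pmp22 and Tcaf1 were each detected on 1 of the pre-DC arrays and Nr1h3 on 1 of the immature DC arrays. Ear10, Sirpb1a and Gm5150 belong to families of near-identical genes, so their probes are uncertain. With the treatment sign turned in pre-DC, immature DC or mature DC, 12, 0 and 2 genes reached the limit. For the first of these, independent pairs would give 0.377 higher and 0.297 lower. The count for independent pairs can thus be exceeded without a shared direction, and the excess does not measure a treatment effect. Without background correction 2 genes reached this limit, with the authors' processed values 3, with an offset of 50 8 and with the mean of all probes 9, and at 2-fold there were 0.

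**Figure D2:**
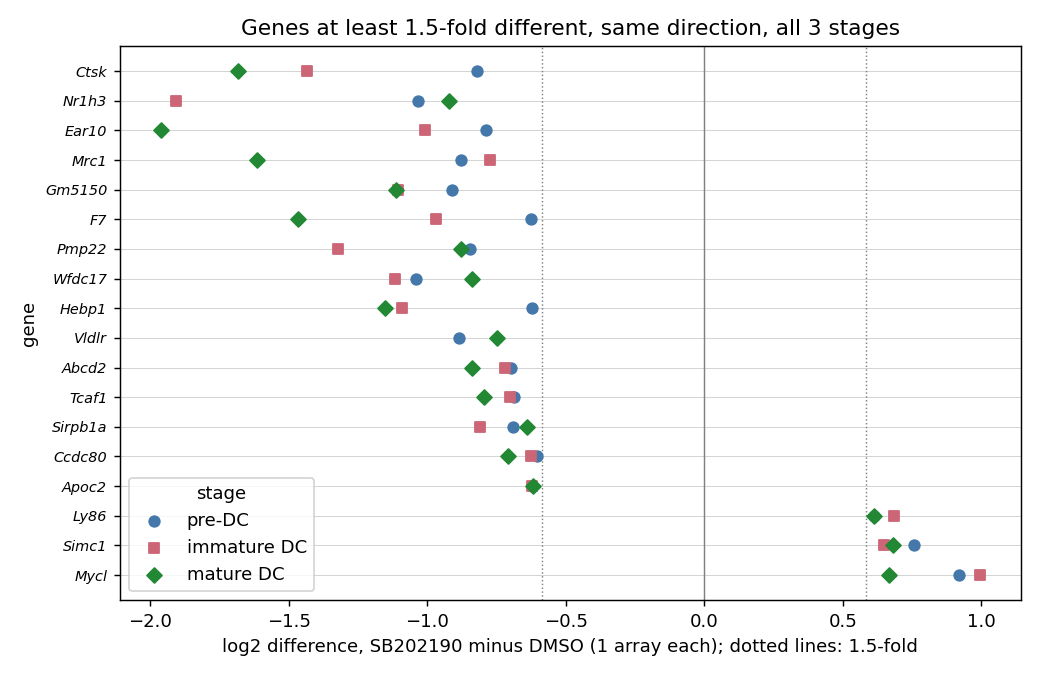
Log2 difference (SB202190 minus DMSO) in each stage of the 18 genes that differed at least 1.5-fold in the same direction in all 3 stages; the dotted lines mark 1.5-fold and a point is left out where neither array detected the gene. Ctsk lies at -0.82, -1.43 and -1.68 and Mycl at 0.92, 0.99 and 0.67 in pre-DC, immature DC and mature DC.

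After 2 days of culture, the maturation genes Fscn1, Cd83 and Il4i1 were lower on the SB202190 array, and the complement genes C1qb and C1qc and the DC identity list (median log2 difference 0.40) higher. Fscn1, an actin-bundling protein of mature DC, was 4.76-fold lower, Cd83 4.65-fold lower and the secreted amino acid oxidase gene Il4i1 3.72-fold lower. The size for Fscn1 depended on background correction. Its log2 difference of -2.25 became -0.99 without background correction and -1.12 with the authors' processed values. The protease inhibitor genes Stfa2 and Stfa1 of the neutrophil list were 3.63-fold and 2.27-fold lower, though genes of this family are near-identical and their probes uncertain. C1qb was 2.63-fold higher and C1qc at least 2.12-fold higher, both genes of the complement component C1q. Among DC genes, the lectin Cd209a was 2.22-fold higher and Zbtb46, a transcription factor of conventional DC, at least 2.08-fold higher, and Map2k6, a kinase that activates p38, was at least 2.80-fold higher.

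In this pair 14 genes were at least 2-fold higher and 40 at least 2-fold lower of 8882. Here and in the later stages, places among random lists are descriptive, since the limits are too narrow for genes that vary together. Lists with a median below all but 2.5% of random lists were costimulation and maturation (-0.20, 9 of 16 genes lower), PPARG and lipid targets (-0.12), monocyte (-0.29), eosinophil (-0.50) and neutrophil (-0.06) markers, glycolysis (-0.08) and oxidative stress (-0.08). Markers of other marrow cells were also below it, with medians of -0.72 for B cells (7 of 7 lower), -0.72 for T cells, -0.45 for plasmacytoid DC (7 of 7 lower) and -0.47 for erythroid cells. Above all but 2.5% lay DC identity (0.40), MHC class II presentation (0.26), interferon response (0.14) and ERK feedback genes (0.12). The median and mean differed in sign for macrophage markers (-0.02 and 0.09), stress genes (0.031 and -0.020), progenitor markers (-0.048 and 0.012) and ribosomal proteins (-0.0081 and 0.0037). A single array on each side gives no replicate check, and the median of the costimulation list turned to 0.02 with the mean of all probes, that of the interferon list to -0.0090 with the mean of all probes and to -0.00085 without the detection filter. The total of 54 genes became 6 without background correction, 10 with the authors' processed values and 22 with an offset of 50.

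In immature DC, costimulation and DC genes were higher with SB202190 and proliferation genes lower. Cd40 was 2.37-fold, Fscn1 2.04-fold, Cd86 1.86-fold, Cd83 1.67-fold, Ccr7 1.67-fold and Tnfsf4 1.43-fold higher. The lectins Cd207 (langerin) and Cd209a were 3.70-fold and 2.75-fold higher and the peptidase Dpp4 2.23-fold higher. Among the genes furthest lower were Car4, a carbonic anhydrase (4.26-fold lower), Nr1h3 (at least 3.72-fold lower), Fos, an immediate early gene (2.90-fold lower), and Gpx3, a glutathione peroxidase (2.85-fold lower). All 28 measured cell cycle genes were lower, among them the thymidylate synthase Tyms (2.05-fold).

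Here 53 genes were at least 2-fold higher and 47 at least 2-fold lower of 8945. Lists above all but 2.5% of random lists were costimulation and maturation (median 0.35, 16 of 19 higher), DC identity (0.49), NF-kB members and targets (0.31, 19 of 21 higher), interferon response (0.28) and MHC class II presentation (0.20). Below all but 2.5% were cell cycle (-0.60), neutrophil and granule markers (-0.49, 18 of 21 lower), monocyte markers (-0.60), eosinophil markers (-0.80, 5 of 5 lower), PPARG and lipid targets (-0.26), cholesterol synthesis (-0.35, 15 of 16 lower), inflammatory cytokines (-0.34), chemokines and receptors (-0.33) and oxidative stress (-0.14). The granule gene Ms4a3 had a log2 difference of -1.32 beside the lower proliferation genes. The median and mean differed in sign for macrophage markers (0.07 and -0.06) and ribosomal proteins (-0.011 and 0.036). Markers of other cells above all but 2.5% of random lists were those of T cells (0.65), NK cells (0.69), plasmacytoid DC (0.51), mast cells and basophils (0.29), progenitors (0.32) and stroma (0.59). The total of 100 genes became 17 without background correction, 25 with the authors' processed values, 40 with an offset of 50 and 55 with the mean of all probes, and the pair has no replicate.

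In mature DC, costimulation genes were higher with SB202190, macrophage and lysosome genes lower. Of 20 measured costimulation genes 19 were higher (median 0.77), among them Fscn1 (2.44-fold), Slamf1 (2.35-fold), Cd70, the CD27 ligand (2.15-fold), Cd200 (2.06-fold), Tnfsf4 (1.99-fold), Cd40 (1.95-fold), Cd83 (1.84-fold), Cd80 (1.73-fold) and Cd86 (1.64-fold). The antiviral gene Oasl1 was 2.65-fold higher, the interferon-inducible gene Ifi205 at least 2.18-fold higher and Irf8, a transcription factor of DC, 2.16-fold higher. Lower were Ear10 (3.89-fold), Plxnb2 (3.82-fold), Ctsk (3.21-fold), Mrc1 (3.06-fold), the clotting factor gene F13a1 (2.49-fold), the lipid carrier gene Apoe (2.26-fold), Pparg (2.17-fold) and Clec9a, a lectin of cross-presenting DC (2.17-fold). Members of the Ear and Rnase2a family are near-identical, so their probes are uncertain.

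This pair held 84 genes at least 2-fold higher and 87 at least 2-fold lower of 8940. Besides costimulation, DC identity (median 0.23), NF-kB members and targets (0.22), interferon response (0.25) and MHC class I presentation (0.22, 12 of 14 higher) lay above all but 2.5% of random lists, as did progenitor (0.76) and mast cell and basophil (0.48) markers. Below all but 2.5% were macrophage markers (-0.39, 15 of 19 lower), lysosome and autophagy (-0.35, 19 of 23 lower), monocyte markers (-0.35), PPARG and lipid targets (-0.30, 15 of 18 lower) and cell cycle (-0.17). The median and mean differed in sign for eosinophil markers (0.05 and -0.26), plasmacytoid DC markers (0.14 and -0.01), MHC class II presentation (-0.0022 and 0.022) and cholesterol synthesis (0.0012 and -0.0059). The total of 171 genes became 12 without background correction, 24 with the authors' processed values, 47 with an offset of 50, 93 with detection on both arrays and 85 with the mean of all probes. There is again no replicate of the pair, and the SB202190 array had the fewest detected probes of the 6.

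**Figure D3:**
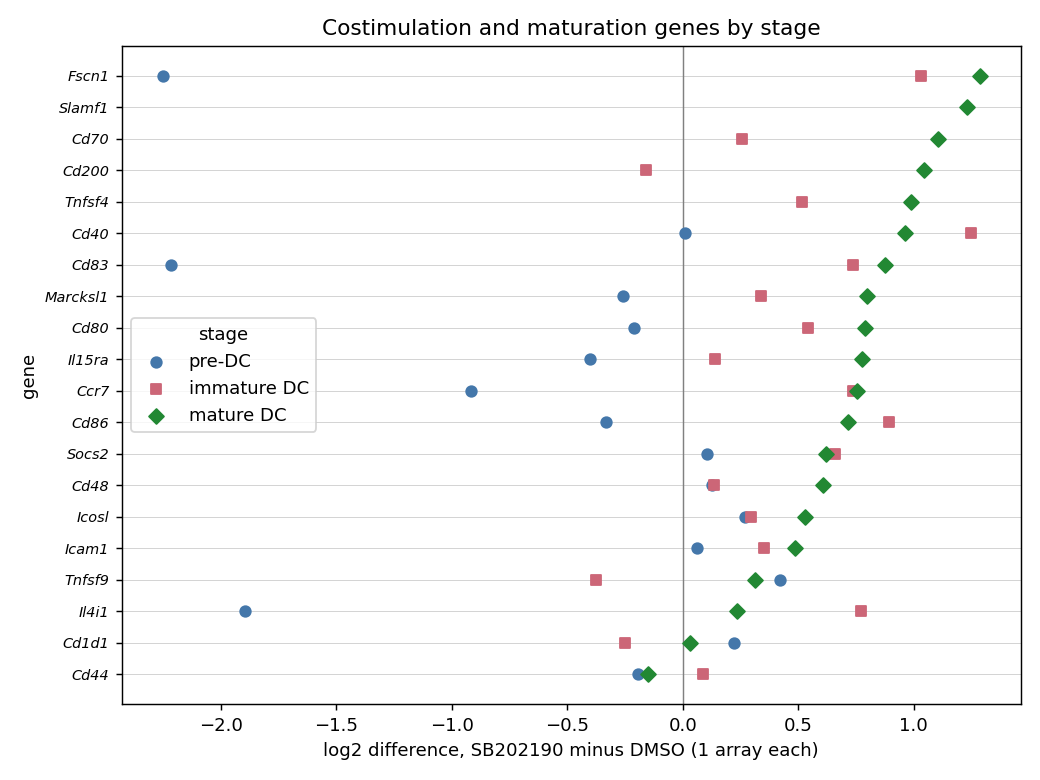
Log2 difference (SB202190 minus DMSO, 1 array each) of the 20 measured costimulation and maturation genes in each stage, with a point left out where neither array detected the gene. Fscn1 lies at -2.25 in pre-DC and at 1.03 and 1.29 in immature and mature DC, and Cd40 at 0.01, 1.25 and 0.96.

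Across 9221 genes, which are not independent replicates, the differences of immature and mature DC correlated with a Pearson r of 0.34 (Spearman rho 0.30). Those of pre-DC correlated with immature DC at 0.12 (rho 0.14) and with mature DC at -0.03 (rho -0.02).

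From pre-DC to immature DC, MHC class II, macrophage and DC identity genes rose and neutrophil granule and cell cycle genes fell as lists in camera. None of these calls held with an estimated correlation. That setting called 0 of the 31 lists, even where all 28 cell cycle genes passed singly in limma, so it decides little. Pre-DC were cells after 2 days of culture and immature DC the semi-adherent cells at day 7. Changes within cells therefore cannot be told apart from a change in the mix of cells. The erythroid list did not pass (camera adjusted p = 0.204). The nonclassical class I gene H2-M2 rose by 7.26 on the log2 scale (SE 0.51, limma adjusted p = 0.000383), the complement gene C1qc by 6.37 (SE 0.29), the chemokine Ccl5 by 5.71 (SE 0.34), Fscn1 by 5.26 (SE 0.83) and Ccr7 by 4.98 (SE 0.42). Arg1, the arginase of alternatively activated macrophages, was at least 54.6-fold higher. The haemoglobin gene Hbb-bt fell by 6.84 (SE 0.28), the granule protease genes Ctsg by 5.79 (SE 0.17), Elane by 5.68 (SE 0.13) and Prtn3 by 5.55 (SE 0.30), the myeloperoxidase gene Mpo by 5.44 (SE 0.20) and the B cell receptor gene Cd79b by 4.98 (SE 0.20). Haemoglobin and H2 genes belong to families of near-identical genes, so their probes are uncertain.

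In limma 2357 genes rose and 2344 fell, of which 1107 and 925 changed at least 2-fold. Camera called 17 lists, 11 up and 6 down. All 14 measured MHC class II genes rose (median 1.72, camera adjusted p = 9.8e-07), as did 15 of 19 macrophage markers (median 2.01, adjusted p = 1.27e-06), 16 of 20 costimulation genes (median 1.82, adjusted p = 1.39e-05), 13 of 18 DC identity genes (median 1.40, adjusted p = 6e-05) and 15 of 23 lysosome and autophagy genes (median 0.75, adjusted p = 2.95e-04). All 28 cell cycle genes fell (median -1.47, adjusted p = 4.66e-09), with 20 of 22 neutrophil and granule markers (median -3.30, adjusted p = 5.72e-10), 10 of 10 mast cell and basophil markers (median -1.75, adjusted p = 5.98e-05) and 6 of 7 B cell markers (median -2.36, adjusted p = 0.00713). Adjusted over the list alone, 14 class II, 16 macrophage, 16 costimulation, 13 DC identity and 17 lysosome genes passed as higher, and 28 cell cycle, 20 neutrophil, 10 mast cell and 6 B cell genes as lower. With an estimated correlation 0 of the 31 lists were called: the adjusted p = 0.423 with an estimated correlation for MHC class II, macrophage, DC identity, neutrophil and mast cell lists, 0.437 for cell cycle and lysosome, 0.443 for costimulation and 0.498 for B cells, while fry called 23.

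The other 6 rising lists were chemokines and receptors (9 of 16 genes, median 1.04, camera adjusted p = 0.00713), ERK feedback and immediate early genes (15 of 24, median 0.69, adjusted p = 0.00713), glycolysis (10 of 14, median 0.59, adjusted p = 0.00244), MHC class I presentation (10 of 14, median 0.71, adjusted p = 0.00641), NF-kB members and targets (11 of 21, median 0.43, adjusted p = 0.0328) and PPARG and lipid targets (9 of 18, median 0.43, adjusted p = 0.0328). Unfolded protein and amino acid stress genes fell (11 of 16, median -0.67, adjusted p = 0.00371), as did progenitor markers (6 of 10, median -0.78, adjusted p = 0.0372). Adjusted over the list alone, 9 chemokine, 16 ERK, 10 glycolysis, 12 class I, 12 NF-kB and 10 PPARG genes passed as higher and 11 stress and 6 progenitor genes as lower. The adjusted p = 0.423 with an estimated correlation for chemokines, ERK, glycolysis, stress and progenitor genes, and the adjusted p = 0.437 with an estimated correlation for the remaining lists. Among lists that did not pass, the median, mean and test differed in sign for inflammatory cytokines (median -0.07, mean 0.17, tested up), NK cell markers (0.18 and -0.55, down) and plasmacytoid DC markers (0.91 and -0.33, up). Without the immature DC array with SB202190 the gene count was 2588, and without either pre-DC array 1 list each no longer passed (PPARG and lipid targets, adjusted p = 0.077, without DMSO, and NF-kB, adjusted p = 0.058, without SB202190). Single settings made 2 further lists pass: interferon response as higher without the detection filter (adjusted p = 0.0474) or the pre-DC array with DMSO (0.0406), and erythroid markers as lower without the pre-DC array with SB202190 (0.0317). The progenitor call ended in 4 alternatives, at adjusted p = 0.072 without background correction, 0.060 with the authors' processed values, 0.527 with detection on all arrays and 0.069 with the mean of all probes.

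From immature to mature DC, NF-kB, glycolysis and costimulation genes rose and cell cycle and neutrophil granule genes fell as lists in camera. None of these calls held with an estimated correlation, which again called 0 of the 31 lists and so decides little. No array had the further 48 h of culture without TNF-a and IL-1b, so their effect cannot be told apart from that of culture time. The inflammatory cytokines did not pass as a list (camera adjusted p = 0.247): in limma 7 of its 13 members rose and 4 fell. Acod1, the itaconate-producing enzyme of activated myeloid cells, rose by 4.09 on the log2 scale (SE 0.26, limma adjusted p = 0.00144), the chemokine Cxcl1 by 3.75 (SE 0.25), the cytokine Il1b by 2.78 (SE 0.17) and Tnfsf4 by 1.58 (SE 0.25). The interleukin-12 subunit gene Il12a was at least 6.83-fold higher and the nitric oxide synthase gene Nos2 at least 4.85-fold higher. Mpo had a log2 change of -4.05 (SE 0.20), Mrc1 -3.29 (SE 0.23) and the lectin Mgl2 -2.90 (SE 0.23), and Cd209c was at least 13.2-fold lower. Pparg fell by 0.72 (SE 0.19, limma adjusted p = 0.0448). Cd83 (1.12, limma adjusted p = 0.325), Ccr7 (1.34, limma adjusted p = 0.0731), Cd86 (0.73, limma adjusted p = 0.143) and Cd80 (0.77, limma adjusted p = 0.0815) did not pass. Without either pre-DC array all 4 passed (adjusted p = 0.00103 for Cd83, 0.000395 for Ccr7, 0.00944 for Cd86 and 0.00793 for Cd80). Without background correction, with the authors' processed values or with an offset of 50, Ccr7 (0.0067 to 0.0138) and Cd80 (0.0317 to 0.0386) passed, and Cd80 also with the mean of all probes (0.0326). Tnfsf4 no longer passed without the immature DC array with DMSO (0.0672) or SB202190 (0.0524) or the mature DC array with SB202190 (0.0593). Pparg no longer passed without those arrays (0.190, 0.192 and 0.189), without the detection filter (0.0706) or with the mean of all probes (0.162).

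In limma 964 genes rose and 1022 fell, of which 381 and 462 changed at least 2-fold. Camera called 9 lists. The rising lists were NF-kB members and targets (14 of 21 genes, median 0.75, camera adjusted p = 7.05e-07), glycolysis (9 of 14, median 0.60, adjusted p = 5.77e-06), costimulation (10 of 20, median 0.93, adjusted p = 2.27e-04), oxidative stress (6 of 17, median 0.36, adjusted p = 6.77e-04), interferon response (4 of 20, median 0.36, adjusted p = 0.00621) and inhibitory genes (8 of 18, median 0.52, adjusted p = 0.018). Falling were cell cycle (24 of 28, median -1.58, adjusted p = 1.09e-13), neutrophil and granule markers (15 of 22, median -1.58, adjusted p = 2.75e-06) and cholesterol synthesis (6 of 16, median -0.45, adjusted p = 0.00621). Adjusted over the list alone, 14 NF-kB, 11 glycolysis, 12 costimulation, 7 oxidative stress, 4 interferon and 9 inhibitory genes passed as higher, and 25 cell cycle, 15 neutrophil and 10 cholesterol genes as lower. None was called with an estimated correlation: the adjusted p = 0.585 with an estimated correlation for NF-kB, glycolysis, oxidative stress, interferon and inhibitory genes, 0.763 for cell cycle and neutrophil markers and 0.876 for costimulation and cholesterol, while fry called 6. Among lists that did not pass, the median, mean and test differed in sign for p38 MAPK pathway genes (median 0.04, mean -0.09, tested down), ERK feedback genes (0.13 and -0.25, down), DC identity (0.05 and -0.22, down) and erythroid markers (-0.11 and 0.02, down). The inhibitory list was not called on ranks (adjusted p = 0.0652) or with detection on all arrays (adjusted p = 0.241). Without the immature DC array with DMSO or SB202190 the gene count was 572 and 797, without the mature DC array with DMSO or SB202190 it was 858 and 670, and without the immature DC array with DMSO the cholesterol list had an adjusted p of 0.068. Macrophage markers passed as lower without background correction (adjusted p = 0.0407), without the detection filter (0.0105) and without the mature DC array with DMSO (0.0115). Eosinophil and mast cell markers passed as lower without the detection filter (adjusted p = 0.0201 and 0.00862) and without either pre-DC array (0.0417 for both). Eosinophil markers also passed without the SB202190 array of immature DC (0.00567) or mature DC (0.00246), and mast cell markers without the immature DC array with DMSO (0.0316) or the mature DC array with SB202190 (0.00943). Lysosome and autophagy genes passed as higher without the mature DC array with SB202190 (0.0256).

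Maturation was also followed within each treatment, with 1 array at each point and no test. Costimulation genes had a median change of 0.82 with DMSO and 1.07 with SB202190, and 15 of the 20 had the larger difference with SB202190. Cell cycle genes had medians of -1.89 with DMSO and -1.19 with SB202190, and 25 of the 28 were less negative with SB202190. Neutrophil and granule markers likewise had -1.91 and -1.46. For each gene, the change with SB202190 less that with DMSO equals the mature DC pair difference less the immature DC one. It is therefore no separate result. In the immature and mature DC pairs the medians were -0.60 and -0.17 for cell cycle, -0.49 and -0.04 for neutrophil markers, and 0.35 and 0.77 for costimulation. The first 2 lists thus started lower on the immature DC array with SB202190. The median over genes of the change with SB202190 less that with DMSO lay above all but 2.5% of random lists for costimulation (0.25), cell cycle (0.48), neutrophil (0.25), monocyte (0.24) and eosinophil (0.91) markers, cholesterol synthesis (0.32), cytokines (0.31), chemokines (0.27) and MHC class I presentation (0.16). It lay below all but 2.5% for MHC class II presentation (-0.18, 2 of 14 larger with SB202190), lysosome and autophagy (-0.19) and macrophage (-0.28), mast cell and basophil (-0.38), plasmacytoid DC (-0.45) and stromal (-0.89) markers. Of 9465 genes, 459 were at least 2-fold higher after maturation with DMSO and 435 with SB202190, with 283 in both, and 540 and 520 were at least 2-fold lower, with 337 in both. The differences correlated across genes with a Pearson r of 0.80 (Spearman rho 0.70). The change differed at least 2-fold between the treatments for 153 genes in favour of SB202190 and 137 in favour of DMSO, a total of 290 that became 7 without background correction, 17 with the authors' processed values, 44 with an offset of 50, 93 with detection on all 4 arrays and 156 with the mean of all probes.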

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

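The tests of marker cells, of processing settings and of already matured cells in this part were chosen only after the results they measure had been seen. The results below differ between stages in direction, and none of these differences was tested, because each stage has 1 array for each treatment.

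Fscn1 had a log2 difference (SB202190 minus DMSO) of -2.25 in pre-DC and 1.03 and 1.29 in immature and mature DC, so the later differences lie 3.28 and 3.54 above the earlier one. Pnkd had -1.58, 1.05 and 1.03, gaps of 2.63 and 2.60. Pacsin1 had -1.58 in pre-DC and 1.08 in immature DC, a gap of 2.66, and Bex2 had -1.29 in immature DC and 1.10 in mature DC, a gap of 2.39. Over the 5 alternatives that change a gene's value the smallest of these gaps were 1.99 and 2.25 for Fscn1 (no background correction), 0.92 and 1.15 for Pnkd and 0.79 for Pacsin1 (mean of all probes), and 0.76 for Bex2 (no background correction). The median of the T cell markers moved from -0.72 in pre-DC to 0.65 in immature DC, a gap of 1.36, and that of the plasmacytoid DC markers from -0.45 to 0.51, a gap of 0.96. These medians cover 5 and 3 measured T cell markers (mean 0.18 over the 3) and 7 and 6 plasmacytoid markers, so the gaps compare different genes.

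The costimulation and maturation list had a median of -0.20 in pre-DC, 0.35 in immature DC (0.55 above) and 0.77 in mature DC (0.97 above), over 16, 19 and 20 measured genes. In the later stages the lowest list median over the 7 alternatives was 0.25, and the medians stayed above all but 2.5% of random lists in the 5 that change a gene's value. Most settings shrink a difference without turning it, so the kept sign decides little, and the random-list limits are too narrow for genes that vary together. The medians of immature and mature DC were 0.31 and 0.66 without background correction and 0.34 and 0.76 with 75th percentile scaling. These sizes argue against either step as the whole source in the later stages. In pre-DC processing is not argued against, since the median was 0.021 with the mean of all probes. The test was split between stages once that value was known. Fewer B, T and plasmacytoid cells in the SB202190 pre-DC culture stay a candidate explanation there: 18 of 19 markers of those cells were lower, with a median of -0.72, below that of the list. The rule compared medians alone, however. Fscn1, at -2.25, fell further than the lowest of the markers, Pacsin1 at -1.58, so the test does not account for the members of the list furthest lower. Fewer cells that had already matured in the SB202190 pre-DC culture may contribute and cannot be told apart from an effect within cells: the median of 310 genes that were 2-fold higher after maturation lay at the 0.09 percentile of random lists, but it was -0.02 with 142 members higher and 168 lower, which decides nothing. Members of the costimulation list were taken out of those genes after the whole set had been seen to lie below the 2.5th percentile, which the rule first written would have counted in favour of this explanation, and a direct effect of the inhibitor in the progenitors stays open and untested.

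Outside the named genes, 7 probes that are unnamed here differed at least 1.5-fold in the same direction in all 3 pairs, 1 higher and 6 lower, of 2279 detected, where 0.141 and 0.154 would be found if the pairs were independent. No count with a turned sign was made for these probes. Among the named genes 12 reached the limit with the pre-DC sign turned, so this excess does not measure a treatment effect. At 2-fold, 48, 20 and 32 unnamed probes differed in pre-DC, immature DC and mature DC.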

How the results depend on the processing

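The list tests with an estimated correlation, on ranks and with fry between stages were added only after results had been seen. The counts within a stage depended on how background was corrected. Without background correction they were 6 (pre-DC), 17 (immature DC) and 12 (mature DC), with 2 genes in the same direction in all 3 pairs and 7 that differed in maturation. With the authors' processed values they were 10, 25, 24, 3 and 17, and with an offset of 50 22, 40, 47, 8 and 44. With the mean of all probes the counts for immature DC, mature DC, the same direction and maturation were 55, 85, 9 and 156, and with detection on all arrays those for mature DC and maturation were 93 and 93. At 1.5-fold the stages gave 402, 791 and 1056, and at 2-fold 0 genes went the same way in all 3 pairs. Trend and robust moderation called 1 gene across stages, against 0 in the other alternatives that keep all arrays. An estimated correlation called 0 lists across stages and 0 in each step between stages, and fry 0 across stages. The cause of these differences was not tested, apart from the thresholds. Leaving out arrays gave 0 to 41 genes across stages, 2588 to 4710 for immature DC against pre-DC and 572 to 2543 for mature against immature DC, in fits where a lone array is assumed to vary like the other groups. The number of called lists was 13 to 16, 17 throughout, and 9 to 12 in the same order. Across stages a lone array adds nothing to the treatment estimate, so leaving out 1 array there equals leaving out its pair. Scaling to the 75th percentile moved the share of higher calls by at most 4.71 percentage points. Without background correction higher calls were 3 of 12 in mature DC (84 of 171 before), 7 of 17 in immature DC (53 of 100) and 0 of 2 in the same direction (3 of 18). They were 18 of 47 in mature DC with an offset of 50, and 0 of 3 in the same direction and 7 of 17 in maturation (153 of 290) with the authors' values. The slide as a block was not run, because the files used here name no slides. The stage block pairs the arrays of each stage, and 0 genes passed across stages with it or without it.

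Values whose direction turned did not pass in camera or limma, or had no test, and the cause was not tested. For a list the test compares members with other genes, so its direction can turn while the median keeps its sign. In pre-DC the median of the costimulation list was 0.021 with the mean of all probes, and that of the interferon list -0.00085 without the detection filter and -0.0090 with the mean of all probes. Across stages, erythroid markers had 0.0038 without the filter, Mapkapk2 -0.0043 with 75th percentile scaling and Cd83 0.022 without background correction. From pre-DC to immature DC, cytokines had -0.15 with the mean of all probes and -0.066 in fry, T cell markers -0.25 without the filter, plasmacytoid markers 0.91 with 75th percentile scaling and 0.91 in fry, and ribosomal proteins 0.077 with 75th percentile scaling. From immature to mature DC, the stress list had -0.0065 without background correction, 0.034 with 75th percentile scaling, 0.0021 with the authors' processed values, 0.024 with an offset of 50, -0.22 without the filter, -0.22 with detection on all arrays, -0.048 with the mean of all probes and 0.025 on ranks. With detection on all arrays, ERK genes had 0.13 (also on ranks), DC identity -0.027, monocyte markers -0.29 (-0.44 in fry) and plasmacytoid markers 0.31, and with 75th percentile scaling erythroid markers had 0.043 and H2-Ab1 0.022.

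With 1 array or pair left out, values whose direction turned ranged as follows. Across stages the genes were Ccr7 -0.090 to 0.75, Cd274 -0.072 to 0.24, Mapkapk2 -0.024 to 0.045, Mapk14 -0.12 to 0.013 and Cd83 -0.74 to 0.81, and the list medians mast cell markers -0.0052 to 0.24, B cell markers -0.30 to 0.043, T cell markers -0.11 to 0.0025 and plasmacytoid DC markers -0.54 to 0.19. From pre-DC to immature DC they were inflammatory cytokines -0.11 to 0.023, NK cell markers -0.15 to 0.51 and plasmacytoid DC markers 0.47 to 1.34. From immature to mature DC they were MHC class I presentation 0.075 to 0.20, ERK feedback genes -0.098 to 0.16, stress genes -0.16 to 0.025, monocyte markers -0.75 to -0.12, progenitor markers -0.31 to 0.037, erythroid markers -0.27 to 0.072, B cell markers -0.17 to 0.34, T cell markers -0.35 to 0.11, NK cell markers -0.18 to 0.48, plasmacytoid DC markers -0.78 to 0.26, stromal markers -0.85 to 0.26 and H2-Ab1 -0.20 to 0.12.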

Other observations

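The tests of granule genes, macrophage markers, liver X receptor targets, random lists under other processing and genes kept at 1.5-fold in this part were chosen only after the results they measure had been seen, and the limit for macrophages in mature DC was extended after its median was known.

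Small marker groups outside the DC lineage, described without a test, also differed between the arrays of a stage. The mast cell protease gene Cpa3 was 2.79-fold higher with SB202190 in immature DC and 2.09-fold higher in mature DC, and Kit, the stem cell factor receptor of progenitors and mast cells, 2.18-fold higher in immature DC. Cd93, also on the progenitor list, went the other way, at 2.23-fold and 2.09-fold lower. The serpin gene Serpinf1 was 2.44-fold higher in immature DC and the smooth muscle actin gene Acta2 2.10-fold lower in mature DC. In the maturation step the median of 5 stromal genes changed by 0.09 with DMSO and -0.72 with SB202190.

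Splitting the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. For genes across stages the real split called 0 and the highest of the others 0, so 10 of 10 splits were as large. For lists the real split called 15 and the highest of the others 11, so 1 of 10, the real one, was as large. Of the 10 splits 4 hold 1 array of each stage on each side, as the real one does, and the other 3 of these called 8, 3 and 10 lists. The remaining 6 splits put both arrays of a stage on one side and called 8 to 11. With stage as a block, such a split draws its estimate from the 1 stage it divides. It repeats the pair difference of that stage and is no chance comparison, so only the 4 splits of the real kind can be compared. In these the treatment sign is turned in 1 stage at most, so they too hold part of any treatment effect.

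The cell cycle list was lower in immature DC with SB202190, with a median of -0.60. The highest median over the 7 alternatives was -0.43 (no background correction), and the list's highest percentile among random lists was 0 in the 5 alternatives that change a gene's value. Most of these settings shrink a difference without turning it, so the kept sign decides little. The random-list limits are also too narrow for genes that vary together. The median was -0.43 with background correction left out and -0.60 with 75th percentile scaling in place of quantile normalization. These sizes argue against either step as the whole source. A smaller share of granulocyte progenitors among the SB202190 cells stays a candidate explanation: Elane, Mpo, Prtn3, Ctsg and Ms4a3 had a median of -0.70, at least as low as the cell cycle genes. Slower division within DC was not tested and stays open.

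Of the 15 genes that were 1.5-fold lower in all 3 pairs, 2 stayed so without background correction, 3 with the authors' processed values, 6 with an offset of 50, 7 with the mean of all probes and 15 with 75th percentile scaling, so the part of background correction cannot be told apart from the treatment. That all 15 kept their sign in these settings, a test set out before its outcome was known, decides little, since most of the settings shrink a difference without turning it. In pre-DC and immature DC the macrophage list without those genes had medians of 0.0070 and 0.079 (SD of members 0.60 and 0.50) while the genes had -0.79 and -0.97. By the limit set, these gaps would count against a smaller share of macrophages. They cannot decide it, because the genes were picked for being lower in all 3 pairs and were taken out of the list, so a gap was likely in any case. In mature DC the macrophage median was -0.35 (SD 0.44) beside -0.88 for the genes, so a smaller macrophage share may contribute there and cannot be told apart. For Nr1h3, lower transcription of liver X receptor targets is a hypothesis that stays open: the medians of 11, 15 and 13 measured targets were -0.07, -0.33 and -0.49, at a highest percentile of 7.29 (pre-DC) among random lists, above the 2.5th that was set, and at 88.6, 0.8 and 0.22 without targets that belong to another list.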
